A study of Mus musculus with 6 samples.

How the data were processed

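Cerebellar RNA of 6 mice aged 15 months was analysed, 3 of each genotype, as 1 library per mouse. The authors deposited 1 table of raw read counts, whole numbers per gene and sample, with the coordinates, length, symbol and biotype of 43346 genes on 22 chromosomes per the file headers. Reads were aligned with STAR to mm10, per the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. RNA was extracted with a column kit and libraries followed standard Illumina protocols, per the labels' protocols. Library totals ran from 25245778 to 31135185 counts. Counts limit the precision of low genes, and the spread between mice, a biological coefficient of variation of 11.2%, that of abundant ones.

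The values were tested before use. All 37 mitochondrial genes held 0 counts in every library, so mitochondrially encoded genes were not tested, and any share of mitochondrial reads is unknown. Among genes with more than 100 counts in all, 16 had the same counts as another gene in every library, so at least these models do not give independent values. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and 21 of the 41 genes named by rule overlap another gene of the file, 6 of them a gene with more than 10% of their own counts. A total of 30 symbols read as dates or were unspecified, and these were replaced through their Ensembl identifier where it had a match. Replicates of a genotype differed by more than sampling noise (chi-square per degree of freedom 7.45 to 31.1 over pairs), so none was a copy of another. Replicate numbers follow the order of deposit. Sample titles may code a litter or cage, which the labels do not explain, so no such term was used. Coordinates are those of the file, in mm10.

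Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on genotype (minimum count 10, minimum total 15), which left 16934, and libraries were scaled by TMM. The model held sex and genotype (residual degrees of freedom 3, prior degrees of freedom 5.41) and was fitted by estimateDisp and glmQLFit (robust, legacy version), with the genotype coefficient tested by the two-sided quasi-likelihood F test and p-values adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are KO over WT with edgeR's prior count of 0.125. Their SE is the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, and per-library list medians use log2 CPM with a prior count of 2. The median log2 fold change of all genes moved by 0.0013 between size factors of the RLE type and TMM.

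The test, 34 gene lists, the genes to name and the first set of alternatives were fixed before the data were examined. Lists of cell type markers and pathways were tested with camera against all other genes with a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 5 tested members, and again with an estimated correlation and with fry. Lists of Y-linked genes (4 tested, median log2 fold change -0.06, 0 past the threshold over all genes, adjusted over the list alone or at an unadjusted p under 0.05 in edgeR, 0 in DESeq2 and limma-voom) and of neighbours of Tmem106b stood outside this family (the second is not used, as 3 of its 11 tested members lie on chromosome 12), and 4 brainstem and spinal cord genes were too few to test (median log2 fold change -0.59, with the same counts of 0). Of 775 list entries, 762 were found in the file. Named genes were Tmem106b, the 12 higher and 12 lower genes with the largest fold change at the threshold, with a mean of at least 1 CPM, groups that do not overlap and no provisional or pseudogene name, up to 4 members past the threshold per list, and 15 anchors chosen for the tissue. Some of these genes are not reported here. Neighbours were genes within 10 Mb of Tmem106b, or 5 Mb as an alternative, compared by Fisher's exact test.

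Alternatives were RLE size factors, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's newer quasi-likelihood version, no sex term, males only, each library left out and a threshold of 0.10. Fits with GC content and gene length trends of each library removed as offsets (loess, span 0.5, with GC content known for 99.0% of tested genes from the mouse reference annotation), and fits with each library's choroid plexus score in place of sex, were added after seeing the data. The same steps were tested on simulated counts for 16934 genes of the KO against WT comparison, in 3 runs with 200 changed genes each, drawn from genes with a mean of at least 50 counts. edgeR recovered 67.0% of 1.5-fold and 95.3% of 2-fold changes with 4.13% false calls, DESeq2 67.3% and 92.3% with 6.08%, and limma-voom 65.7% and 94.0% with 4.39%. These counts took each gene's dispersion from the trend alone, without a sex effect, GC trends of libraries or correlation between genes. The rates therefore test the steps and are not the power or false-call rate in the real libraries. Camera called 3 of 3 shifted lists and 0 of 87 unshifted ones, in data simulated without correlation between genes. Figures were drawn with matplotlib 3.10.9.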

Results

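RNA was sequenced from the cerebellum of 15-month-old mice, 3 wild-type (WT) and 3 homozygous for a Tmem106b knockout allele (KO), with 1 female and 2 males per genotype. TMEM106B is a membrane protein of late endosomes and lysosomes, and variants of the human gene modify the risk of frontotemporal dementia. The study asked what the loss of this protein does to the aged cerebellum, and its title names the Purkinje cells, the large inhibitory neurons that form the output of the cerebellar cortex. Each mouse gave 1 library of read counts per gene. The totals were 31135185, 30110110 and 29658618 counts in WT replicates 1 to 3 and 25245778, 28584165 and 27725645 in KO replicates 1 to 3. RNA integrity numbers were 10 in all 6 samples. The first principal component of log2 expression (35.6% of the variance) set WT replicate 1 at -40.1 against -10.8 to 22.0 for the other libraries. The second (26.9%) set KO replicate 1 at 38.5 against -14.4 to 5.98 for the others. The third (17.9%) placed the WT mice between 6.62 and 15.8 and the KO mice between -27.7 and 1.65.

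Tmem106b itself, measured first as a check of the labels, was lower in every KO mouse. Its normalised level was 245 ± 19.4 CPM (counts scaled to the size of each library) in WT and 66.8 ± 3.64 CPM in KO (SD, n = 3 each), so that 27.2% of the WT level remained. The log2 fold change was -1.88 with a standard error (SE) of 0.08, at an adjusted p of 1.37e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The gene (ENSMUSG00000029571) lies on chromosome 6 at 13069759 to 13089269 of the mm10 build, and the reads left in KO were counted over the whole gene model, so the part of the transcript they come from is unknown. Xist gave 18345 counts in WT replicate 1 and 21505 in KO replicate 1, the mice labelled female, and at most 12 in the 4 males. The Y-linked gene Ddx3y gave 1693 to 2100 counts in the males, 0 in the WT female and 1 in the KO female.

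Among the genes that changed, 9 of 23 higher in KO belonged to the microglial lists and 3 to the reactive astrocyte list, and 9 of 25 lower in KO belonged to the Purkinje list. The lysozyme gene Lyz2 rose from 17.6 ± 1.53 to 50.8 ± 8.31 CPM (SD, n = 3 each). The pattern-recognition receptor gene Clec7a rose from 2.00 ± 0.56 to 7.12 ± 0.66 CPM, and the lipoprotein lipase gene Lpl from 2.48 ± 0.37 to 8.21 ± 1.52 CPM (SD, n = 3 each). The Clec7a values are those of the gene model ENSMUSG00000079293, annotated as a polymorphic pseudogene. A second model of Clec7a, which overlaps it (38.3 against 127 mean counts), was not among the changed genes. Gfap, the intermediate filament gene of astrocytes, rose from 195 ± 43.5 to 358 ± 23.4 CPM (SD, n = 3 each). Itpr1, which encodes the inositol trisphosphate receptor of Purkinje cells, fell from 3774 ± 83.2 to 2406 ± 120 CPM. Car8, which encodes a carbonic anhydrase-related protein that binds this receptor, fell from 1907 ± 119 to 1242 ± 150 CPM. Ebf2, a transcription factor gene of a subset of Purkinje cells, fell from 16.2 ± 1.64 to 6.27 ± 1.40 CPM. In all, 48 of 16934 genes tested differed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 23 higher and 25 lower in KO, Tmem106b included. In each of the 48 the 3 KO mice lay on 1 side of the 3 WT mice, which was so for 14.1% of all genes tested where chance gives 10%.

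**Figure D1:**
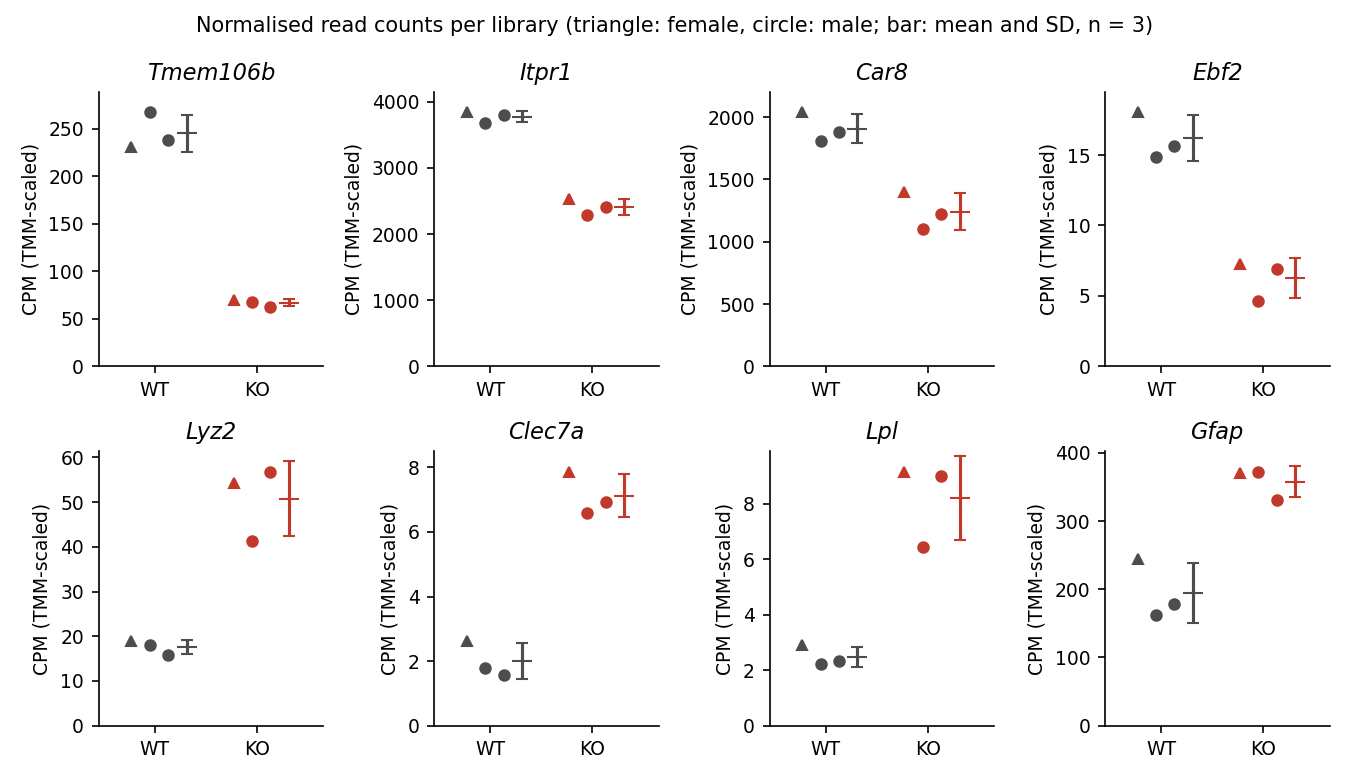
Normalised read counts (CPM, linear axes from 0) of 8 genes in each of the 6 libraries, WT in grey and KO in red, with triangles for females, circles for males and bars for the mean and SD (n = 3). Tmem106b lies at 62.7 to 69.7 CPM in KO and 231 to 267 CPM in WT, and no KO point overlaps a WT point in any panel.

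Among changed genes with a mean of at least 1 CPM and an established name, the 12 higher ones with the largest fold change were Clec7a (log2 fold change 1.85, SE 0.17), Lpl (1.73, SE 0.18), Mslnl (1.67, SE 0.25), Timp1 (1.62, SE 0.23), Lyz2 (1.53, SE 0.13), Ly9 (1.47, SE 0.21), Fcrls (1.46, SE 0.18), Lgals3 (1.29, SE 0.16), Fcgr2b (1.29, SE 0.18), Serpina3n (1.28, SE 0.13), Cd68 (1.26, SE 0.18) and Gpnmb (1.21, SE 0.15). Lgals3 encodes galectin-3 and Fcgr2b an inhibitory Fc receptor. Cd68 encodes a lysosomal glycoprotein of macrophages and Gpnmb a glycoprotein of lipid-laden phagocytes. Under the same rule, with Tmem106b left out, the 12 lower ones were Prl2c3 (-2.07, SE 0.21), Ebf2 (-1.37, SE 0.15), Alpk2 (-1.24, SE 0.13), Sv2c (-0.95, SE 0.14), Camk2a (-0.68, SE 0.08), Sema3a (-0.68, SE 0.09), Arhgef33 (-0.67, SE 0.07), Far2 (-0.67, SE 0.10), Tmem255a (-0.66, SE 0.08), Itpr1 (-0.65, SE 0.07), Rgs8 (-0.65, SE 0.08) and Car8 (-0.62, SE 0.07). Sv2c encodes a synaptic vesicle protein and Camk2a a subunit of calcium/calmodulin-dependent kinase II. Sema3a encodes a secreted guidance protein and Rgs8 a regulator of G protein signalling. Adjusted p-values of these 24 genes in edgeR ran from 0.0106 to 0.0482. The rule also required groups that do not overlap, so in each gene all 3 KO mice showed the direction by selection. Genes named here and further on that did not pass over all genes tested, apart from the anchor genes fixed beforehand, were chosen after their values were seen, as were Doc2b, Ppp1r17 and Dner. Prl2c3 has a close paralog, Prl2c2 (log2 fold change -1.60, SE 0.27, edgeR adjusted p = 0.0656), and Lyz2 has one in Lyz1 (1.52, SE 0.35, edgeR adjusted p = 0.169), so reads within each pair can be shared. Timp1 lies inside the far more abundant Syn1 (6859 against 32.0 mean counts), and Clec7a, Far2, Tmem255a and Grn are among those that also overlap a gene with over 10% of their counts. The number of changed genes was 1 without WT replicate 2 or without WT replicate 3, with Tmem106b the gene left, 16 without KO replicate 2, 93 without WT replicate 1, 117 without KO replicate 1 and 156 without KO replicate 3. It was 218 in DESeq2, 43 in limma-voom and 340 with GC content and length trends removed from each library, an alternative chosen after seeing the data.

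Genes of disease-associated microglia, the state that microglia take around damage and lipid debris, were higher as a group. Of 34 members tested, with Clec7a present as 2 gene models, 6 rose (Lyz2, Clec7a, Lpl, Gpnmb, Lgals3 and Cd68) and 28 did not pass over all genes tested, while 18 were higher adjusted over the list alone. DESeq2 called 15, limma-voom 6 and edgeR with GC and length offsets 16. The median log2 fold change was 0.71, and the per-library medians relative to WT were 0.73, 0.76 and 0.54 in KO against -0.07 to 0.08 in WT. In the same KO libraries red blood cell genes were at 0.58, -0.07 and 0.98 and lymphocyte and neutrophil markers at 1.16, 0.59 and -0.02, against -0.16 to 0.28 and -0.39 to 0.66 in WT. Camera with a preset correlation of 0.01 gave an adjusted p of 1.19e-46 over 30 lists, and this was the only list past the threshold with an estimated correlation (adjusted p = 0.021 with an estimated correlation). In fry its adjusted p was 0.00969. With the preset correlation, camera also called this list in 9 other splits of the libraries into 2 groups (lowest adjusted p = 4.94e-10). Cst7, which encodes cystatin F (log2 fold change 2.57, SE 0.49, edgeR adjusted p = 0.115), Itgax (2.26, SE 0.45, 0.124) and Ccl3 (1.83, SE 0.29, 0.0504) did not pass over all genes. Apoe, at 0.22 (SE 0.13, edgeR adjusted p = 0.684), and Axl, at -0.06 (SE 0.07, 0.858), did not pass either. In edgeR with GC and length offsets, chosen after seeing the data, Apoe (0.36, SE 0.05, adjusted p = 0.00257), Cst7 (2.56, SE 0.48, 0.0396) and Ccl3 (1.78, SE 0.30, 0.0127) passed. Itgax and Axl were not among the calls of that fit.

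Homeostatic microglia markers had a median log2 fold change of 0.41, with 3 of 24 members higher over all genes tested, among them Fcrls and the cathepsin S gene Ctss, and 13 adjusted over the list alone. DESeq2 called 9, limma-voom 2 and edgeR with GC and length offsets 9. Ctss rose from 58.5 ± 4.20 to 93.3 ± 6.04 CPM (SD, n = 3 each). P2ry12 (log2 fold change 0.08, SE 0.14), Tmem119 (-0.01, SE 0.20) and Siglech (-0.01, SE 0.14), receptors and membrane proteins of resting microglia, had edgeR adjusted p-values of 0.884 to 0.993, and Aif1, the gene of the microglial marker Iba1, was at 0.58 (SE 0.17) with an edgeR adjusted p of 0.324. The list's camera call (adjusted p = 1.28e-18) was lost with an estimated correlation (adjusted p = 0.184 with an estimated correlation). Complement genes had a median of 0.57, and of 0.37 without KO replicate 1. In edgeR 0 of 21 members passed over all genes tested, 11 had an unadjusted p under 0.05 and 9 were higher adjusted over the list alone. DESeq2 called 7, limma-voom 0 and edgeR with GC and length offsets 7. The 9 include C3 (1.16, SE 0.18), C3ar1 (1.07, SE 0.18) and C1qb (0.74, SE 0.16), with edgeR adjusted p-values over all genes of 0.0504, 0.0714 and 0.144, and C4b (0.79, SE 0.15, 0.112), whose reads can be shared with its paralog C4a (0.81, SE 0.19, 0.172). With the offsets, chosen after seeing the data, C3, C3ar1, C1qb and C4b passed in edgeR (adjusted p = 0.0051, 0.0171, 7.2e-04 and 0.0134). Camera gave an adjusted p of 6.83e-15 for complement (adjusted p = 0.0645 with an estimated correlation), and its members C1qa, C1qb, C1qc and Itgam are also in the homeostatic list. In fry complement passed (adjusted p = 0.0267) and the homeostatic list did not (0.096).

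**Figure D2:**
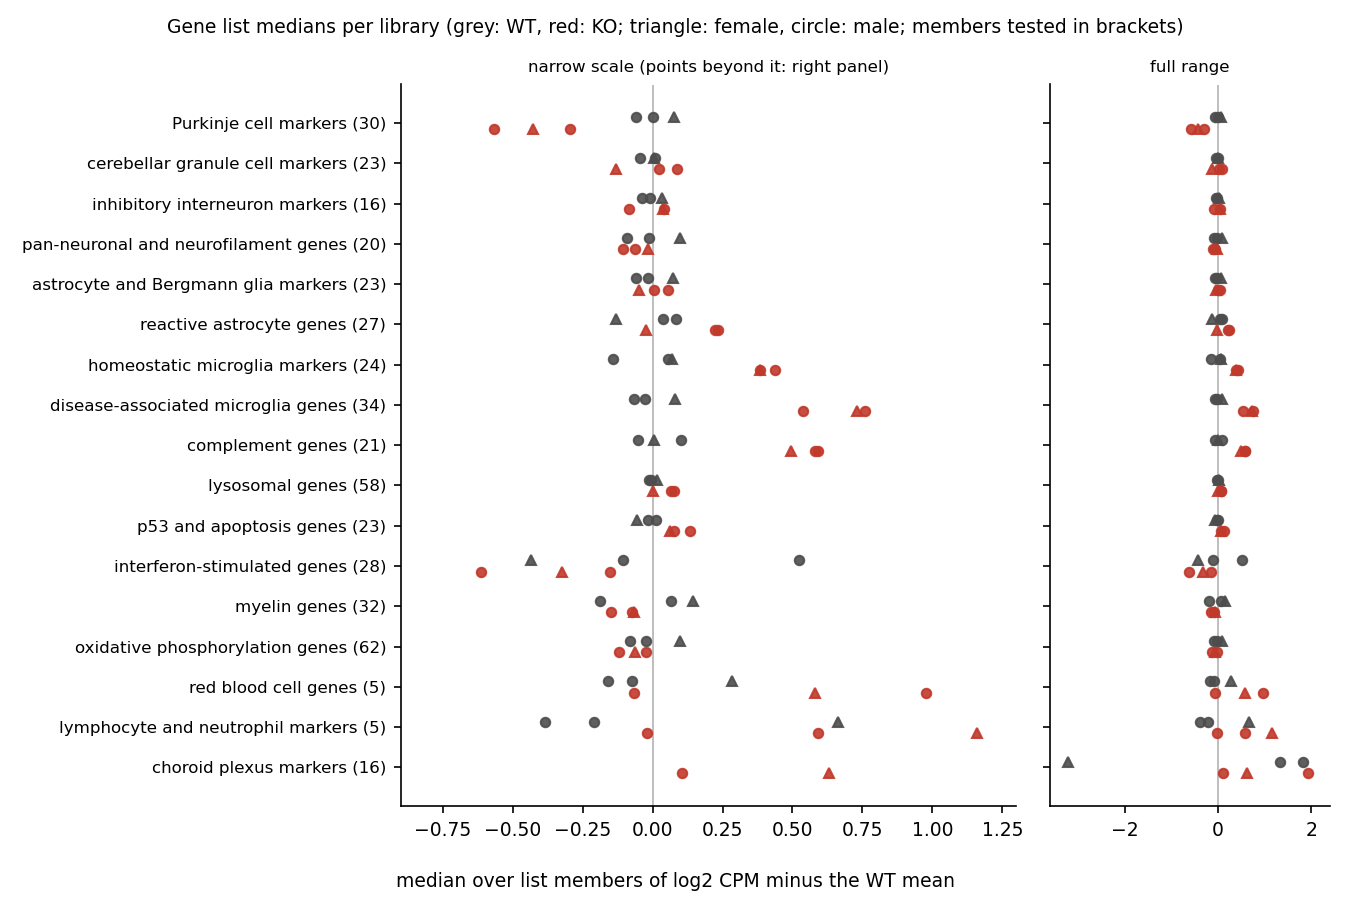
Median over the members of each gene list of log2 CPM minus the WT mean of the gene, per library, with WT in grey, KO in red, triangles for females and circles for males; the right panel shows the full range of the same values. Purkinje cell markers lie at -0.57 to -0.30 in the KO libraries, disease-associated microglia genes at 0.54 to 0.76, and choroid plexus markers run from -3.22 in WT replicate 1 to 1.93 in KO replicate 2.

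Reactive astrocyte genes included 3 higher members of 27 tested and 7 adjusted over the list alone, and DESeq2 called 6 of the 28 members it tested and limma-voom 3. Gfap rose (log2 fold change 0.90, SE 0.11, edgeR adjusted p = 0.0214), and so did the protease inhibitor genes Serpina3n and Timp1. The median of the list was 0.12, with 17 members above 0 and 10 below, and its camera call (adjusted p = 5.94e-07) was lost with an estimated correlation (adjusted p = 0.0935 with an estimated correlation). The list passed in fry (adjusted p = 0.0366). The median was 0.04, 0.34 and 0.07 without WT replicates 1 to 3, 0.03, 0.16 and 0.22 without KO replicates 1 to 3, 0.03 in males only and 0.01 with the choroid plexus score. Lysosomal genes had a median of 0.04 over 58 members, and of 0.07 without WT replicate 1 or KO replicate 3 and 0.06 without KO replicate 1. Over all genes tested 3 rose, each also in a microglial list, among them Ctss and Gpnmb, and 4 were higher adjusted over the list alone. These 4 include the cathepsin D gene Ctsd (0.34, SE 0.07, edgeR adjusted p = 0.118), while the progranulin gene Grn was at 0.09 (SE 0.10, edgeR adjusted p = 0.827) and Lamp1 at -0.05 (SE 0.07, 0.881). Ctsd passed in 6 of 16 alternatives, with adjusted p-values of 0.00201 to 0.578 over the fits in edgeR, DESeq2 and limma-voom, and Grn and Lamp1 in 0. The lysosomal list had a camera adjusted p of 0.00149 (adjusted p = 0.272 with an estimated correlation). Of 23 p53 and apoptosis genes, 1 rose, Hrk, a BH3-only activator of apoptosis in neurons, from 11.3 ± 3.02 to 25.3 ± 6.16 CPM (SD, n = 3 each, edgeR adjusted p = 0.0134). Adjusted over the list alone 2 were higher, Hrk among them. This list had a median of 0.10, and of 0.06 without WT replicate 1 and 0.05 without KO replicate 1, and a camera adjusted p of 0.00306 (adjusted p = 0.184 with an estimated correlation). In fry it passed (adjusted p = 0.0287), while the lysosomal list did not (0.108).

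Purkinje cell markers were lower in KO in all 30 members tested, with a median log2 fold change of -0.44. Over all genes tested 9 fell, among them Itpr1, Arhgef33, Ebf2, Car8, Rgs8, Doc2b, Ppp1r17 and Dner, and 21 did not pass, while 25 were lower adjusted over the list alone. DESeq2 called 18, limma-voom 7 and edgeR with GC and length offsets 19. Ppp1r17, a phosphatase inhibitor of Purkinje cells, fell from 313 ± 6.51 to 223 ± 26.0 CPM (SD, n = 3 each; -0.50, SE 0.07). Calbindin, Calb1, was at 1207 ± 45.8 CPM in WT and 900 ± 137 CPM in KO (SD, n = 3 each; -0.43, SE 0.09, edgeR adjusted p = 0.134), and Pcp2 at -0.64 (SE 0.26, edgeR adjusted p = 0.549). Calb1 passed in 6 of 16 alternatives, DESeq2 among them, with adjusted p-values of 0.00235 to 0.665 over all 16. Males only, without WT replicate 1 and without KO replicate 1 are among the 6 and rest on the same males, so they are not separate support. Pcp2 was at -0.30 without WT replicate 1, -0.31 without KO replicate 1 and -0.91 without KO replicate 3, where it passed, with adjusted p-values of 0.0329 to 0.996 over the alternatives in edgeR, DESeq2 and limma-voom. The KO medians were -0.43, -0.57 and -0.30 against -0.06 to 0.08 in WT. Camera with the preset correlation gave an adjusted p of 1.91e-53, lost with an estimated correlation (adjusted p = 0.109 with an estimated correlation) of 0.385 between members. In fry the list passed (adjusted p = 0.0366). With the preset correlation, camera also called it in 8 other splits of the libraries into groups of equal size (lowest adjusted p = 1.25e-21).

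**Figure D3:**
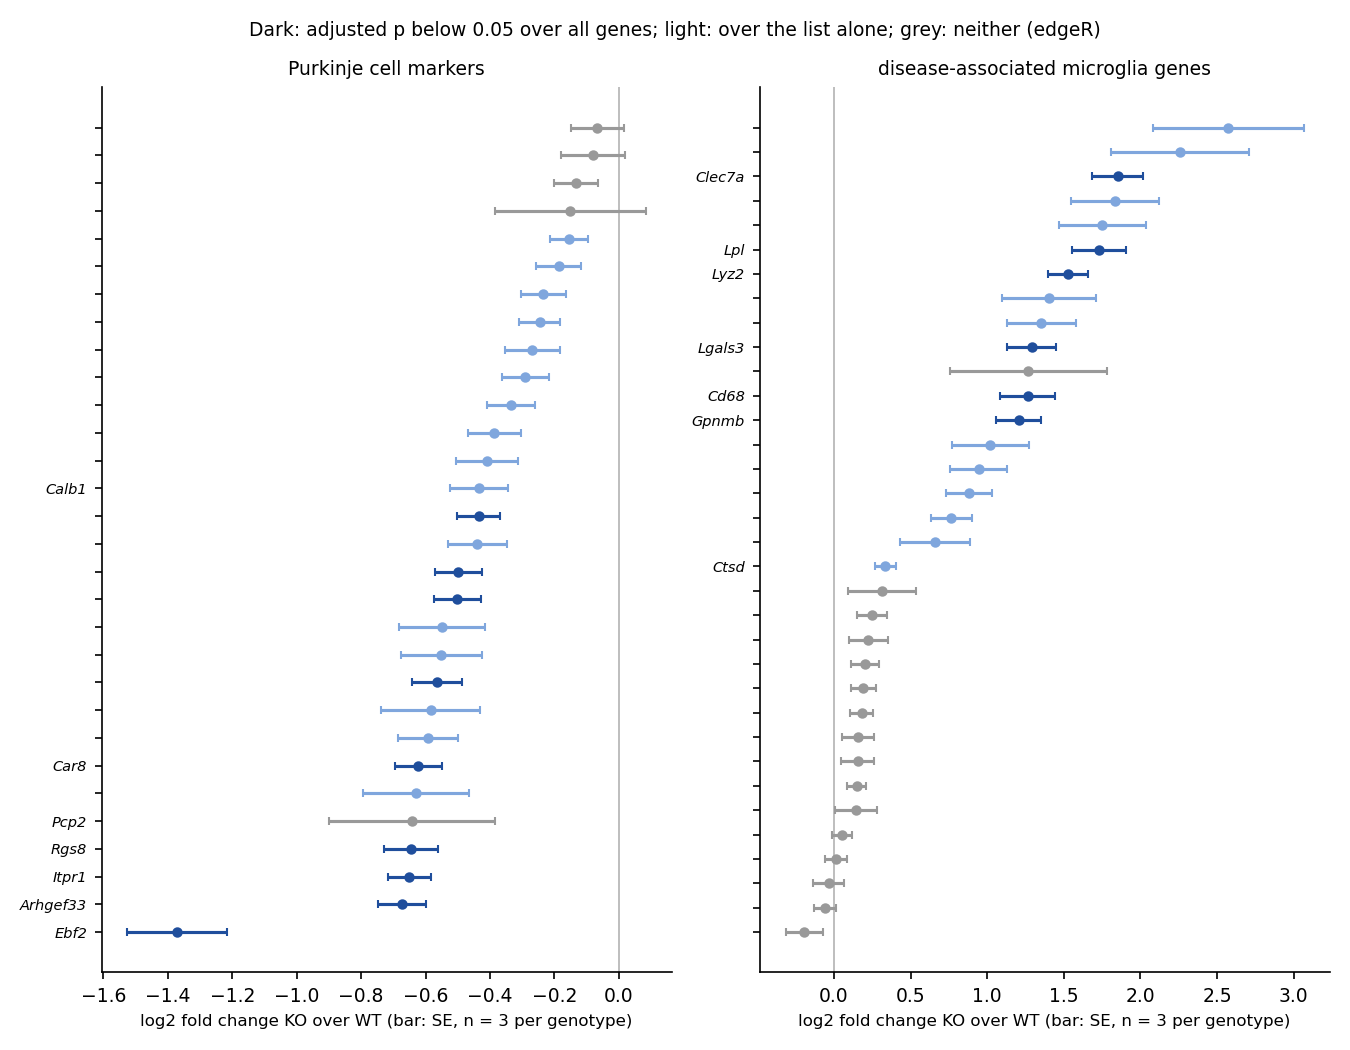
Log2 fold change of KO over WT for every tested member of the Purkinje cell list (left, 30 genes) and the disease-associated microglia list (right, 34 genes, with both gene models of Clec7a), with bars for the SE (n = 3 per genotype), dark points past the threshold over all genes, light points adjusted over the list alone, and labels for genes named by the rule. All 30 Purkinje points lie below 0, from -1.37 for Ebf2 up to -0.07, and 31 of the 34 microglial points lie above 0.

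Markers of the other neurons of the cerebellum did not pass as lists. Granule cell markers had a median of 0.04 over 23 members and a camera adjusted p of 0.279. The receptor subunit gene Gabra6, their anchor, was at 787 ± 33.0 CPM in WT and 851 ± 103 CPM in KO (SD, n = 3 each; 0.11, SE 0.07, edgeR adjusted p = 0.719). The granule list was called higher, at a median of 0.07, in the males alone, without WT replicate 1 and without KO replicate 1, fits that rest on the same males. It was also called, at 0.05, with GC and length offsets, chosen after seeing the data. Its median ran from -0.04 to 0.07 and its camera adjusted p from 0.00382 to 0.951 over 16 alternatives. In edgeR 0 granule members passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Inhibitory interneuron markers (median -0.03, 16 members) and markers of unipolar brush cells and deep nuclei (median 0.20, 9 members) had camera adjusted p-values of 0.279 and 0.0874. The second list was called higher without WT replicate 3 (median 0.28), without KO replicate 3 (0.29) and with a mean of at least 1 CPM (0.24), while its median was 0.10 without WT replicate 2 and 0.06 without KO replicate 2. Its camera adjusted p ran from 0.00613 to 0.612 over the alternatives. In edgeR 0 members of either list passed over all genes, with 2 at an unadjusted p under 0.05 in each, and DESeq2 called 0 and 1 and limma-voom 0. Adjusted over the list alone, 0 interneuron markers and 1 of the other list, Spp1 (0.77, SE 0.14, edgeR adjusted p = 0.0853), were past the threshold. Spp1 is also a member of the disease-associated microglia list. Pan-neuronal and neurofilament genes were lower by camera (median -0.07, 20 members, adjusted p = 0.00149; adjusted p = 0.406 with an estimated correlation), with 0 members past the threshold over all genes in edgeR or limma-voom, 2 at an unadjusted p under 0.05 and 2 in DESeq2. Adjusted over the list alone, 2 were lower, the neurofilament heavy chain gene Nefh (-0.42, SE 0.07, edgeR adjusted p = 0.0565) and Thy1 (-0.43, SE 0.09, edgeR adjusted p = 0.156). The pan-neuronal median was -0.14 without WT replicate 2 and -0.04 without WT replicate 1.

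Lists of myelin, oxidative phosphorylation and interferon-stimulated genes were called lower by camera, with 0 members past the threshold over all genes in edgeR. At an unadjusted p under 0.05 there were 3, 0 and 5 members, and DESeq2 called 1, 0 and 0 and limma-voom 0 in each. Mature oligodendrocyte and myelin genes had a median of -0.10 over 32 members (adjusted p = 0.00543; adjusted p = 0.697 with an estimated correlation), with 1 member, Adamts4, lower adjusted over the list alone, and Mbp at -0.12 (SE 0.15, edgeR adjusted p = 0.864). Mbp changed sign among the 16 alternatives, from -0.29 to 0.11, and passed in 0 of them. Nuclear-encoded oxidative phosphorylation genes had a median of -0.07 over 62 members (adjusted p = 0.00195; adjusted p = 0.761 with an estimated correlation). Interferon-stimulated genes had a median of -0.38 over 28 members (adjusted p = 2.19e-06; adjusted p = 0.697 with an estimated correlation), and their median per library ran from -0.43 in WT replicate 1 to 0.52 in WT replicate 3 and from -0.61 to -0.15 in KO. Adjusted over the list alone, 0 members of the last 2 lists passed. The interferon call was lost without WT replicate 3 (median -0.08, adjusted p = 0.113), the myelin call without WT replicate 1, WT replicate 3, KO replicate 1 or KO replicate 3 (medians -0.04, -0.03, -0.05 and -0.05), and the oxidative phosphorylation call without WT replicate 1 or KO replicate 1 (medians -0.01 and -0.02). The interferon median was -0.59 without WT replicate 1, -0.60 without KO replicate 1 and -0.20 without KO replicate 2, and the myelin median -0.19 without WT replicate 2, with the calls kept. The highest camera adjusted p over the alternatives was 0.697 for interferon and myelin genes and 0.761 for oxidative phosphorylation, and the lowest values were 4.94e-17, 2.10e-06 and 2.44e-05.

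Lists of tissue and blood next to the cerebellum also differed between libraries. Choroid plexus markers, whose median was 3.22 below the WT mean in WT replicate 1, had a median log2 fold change of 0.51 over 16 members (camera adjusted p = 0.00493; adjusted p = 0.761 with an estimated correlation). In edgeR 0 of them passed over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Ttr, their most abundant gene, was at 1.11 (SE 1.62, edgeR adjusted p = 0.881). The list's median turned to -0.26 in the males alone, without WT replicate 1 and without KO replicate 1, fits that rest on the same males. It was 0.92 without WT replicate 2, 1.23 without KO replicate 3 and 0.35 without KO replicate 2, where the call was lost. The choroid plexus median of the KO libraries was 0.63, 1.93 and 0.11. Red blood cell genes had a median of 0.56 over 5 members, 2 of them higher adjusted over the list alone (camera adjusted p = 9.28e-05; adjusted p = 0.432 with an estimated correlation), with library medians of 0.58, -0.07 and 0.98 in KO and -0.16 to 0.28 in WT, and the median was 0.27 without KO replicate 3. Lymphocyte and neutrophil markers had a median of 0.93 over 5 members tested, 2 of them, S100a8 and S100a9, higher adjusted over the list alone (camera adjusted p = 0.0348; adjusted p = 0.343 with an estimated correlation), a call lost in 12 of 15 alternatives and without each library except WT replicate 3. In edgeR 0 members of the blood lists passed over all genes, with 3 red blood cell genes and 2 lymphocyte and neutrophil markers at an unadjusted p under 0.05, and DESeq2 called 1 and 0 and limma-voom 0.

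The remaining lists had camera adjusted p-values of 0.0616 to 0.958 and 0 members past the threshold over all genes in edgeR or limma-voom. They had 0 to 7 members at an unadjusted p under 0.05, the most among astrocyte and Bergmann glia markers, and DESeq2 called 1 of those and 1 immediate early gene. Their median log2 fold changes were -0.02 for astrocyte and Bergmann glia markers, 0.01 for antigen presentation, -0.03 for oligodendrocyte precursors and -0.05 for cholesterol biosynthesis. They were -0.04 for the V-ATPase, -0.02 for autophagy, -0.08 for the unfolded protein and integrated stress responses and -0.20 for immediate early genes, where the mean (0.01) and camera pointed up. They were 0.09 for endothelial, -0.03 for pericyte and smooth muscle and 0.15 for meningeal fibroblast markers, -0.19 for forebrain and midbrain genes and -0.01 for frontotemporal dementia and TMEM106 family genes. Adjusted over the list alone, the astrocyte list had 1 higher and 1 lower member, immediate early genes 1 higher, Jun (0.72, SE 0.12, edgeR adjusted p = 0.0718), forebrain and midbrain genes 1 lower, and the others 0. Leaving out WT replicate 2 gave a call for meningeal markers (median 0.33) and stress responses (-0.12), leaving out KO replicate 3 one for meningeal markers (0.29), and leaving out WT replicate 3 one for pericyte markers (-0.13). Meningeal markers were also called without the low-count filter (0.15). Several of these medians changed sign among the 16 alternatives, for example from -0.03 to 0.33 for meningeal markers, -0.23 to 0.22 for immediate early genes, -0.16 to 0.19 for antigen presentation, -0.13 to 0.07 for pericyte markers and -0.27 to 0.03 for forebrain and midbrain genes. The paralogs Tmem106a and Tmem106c were at 0.68 (SE 0.23, edgeR adjusted p = 0.403) and 0.04 (SE 0.08, edgeR adjusted p = 0.909).

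Genes that flank Tmem106b were examined because a targeted allele can carry sequence of another strain or affect its neighbours. Of the 62 genes tested within 10 Mb, Tmem106b left out, 0 passed in edgeR, against 47 of 16871 elsewhere (two-sided Fisher exact test, p = 1). At the rate found elsewhere, 0 among 62 genes is the likely count, so this test cannot decide whether the flanks differ. Within this window 13 genes had an unadjusted p under 0.05, which became 4 of 63 without KO replicate 2, 8 of 63 without WT replicate 3, 9 of 62 without WT replicate 2 and 12 to 14 of 64 without each of the others, and DESeq2 called 1 and limma-voom 0. edgeR called 1 without the low-count filter and 3 with GC and length offsets, Thsd7a, Glcci1 and Foxp2, in fits chosen for this question after seeing the data. In the main fit Thsd7a was at -0.32 (SE 0.08, edgeR adjusted p = 0.181) and Glcci1 at 0.34 (SE 0.07, edgeR adjusted p = 0.124). A list of neighbours fixed beforehand is not used, because Scin, Arl4a and Etv1 of its 11 tested members lie on chromosome 12 in the mouse.

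Whether the genotype effect differed between the sexes could be asked of a single female per genotype, assumed to vary like the males. The smallest Benjamini-Hochberg adjusted p for the interaction in edgeR was 0.0706 (1700048O20Rik, difference of log2 fold changes, female minus male, 2.93, SE 0.30). Nr1d1 (-0.89, SE 0.11), Airn (-1.99, SE 0.26) and Dbp (-0.87, SE 0.12) came next, at 0.0844. Many further genes shared that value, so no group of genes was singled out. The genes named here were chosen after their values were seen. No gene passed in edgeR at an adjusted p under 0.05, where 3189 of 16934 had an unadjusted p under 0.05, while DESeq2 called 532 and limma-voom 0. edgeR called 1584 without the low-count filter 1 with RLE size factors and 3 with GC and length offsets, where 1250 had an unadjusted p under 0.05, an alternative chosen after seeing the data. In KO replicate 1, the KO female, the deviation of log2 expression from the mean of the 6 libraries had a Spearman correlation of -0.613 with GC content across genes.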

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

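Tmem106b kept its direction and its side of the threshold in all 16 alternatives, at -1.96 to -1.80. The number of changed genes, 48 here, was 75 with RLE size factors, 199 without the low-count filter, 76 with a mean of at least 1 CPM, 218 in DESeq2, 111 in males only and 109 at a threshold of 0.10. It was 340 with GC and length offsets, an alternative chosen after seeing the data, as was the choroid plexus score. Leaving out 1 library gave from 1 to 156 genes, with 1 without WT replicate 2 or WT replicate 3, 16 without KO replicate 2, 93 without WT replicate 1, 117 without KO replicate 1 and 156 without KO replicate 3. All 48 genes kept their direction in every fit that tested them. Their groups do not overlap and the same libraries were refitted, so a kept direction was close to given. All 48 were also called in DESeq2, 41 in limma-voom and 36 without a sex term. Higher genes made up 47.9% of calls here, 36.0% in males only, 38.1% in DESeq2, 63.9% with the choroid plexus score (39 higher, 22 lower), 35.0% without KO replicate 1 and 68.8% without KO replicate 2 (11 higher, 5 lower). The 14 lists became 1 with an estimated correlation, that of disease-associated microglia, and 5 in fry, and were 12 to 15 in the other alternatives. Fry kept the disease-associated microglia, complement, p53 and apoptosis, Purkinje and reactive astrocyte lists. Choroid plexus markers turned to medians of -0.26 in males only, -0.26 without WT replicate 1, -0.26 without KO replicate 1 and -0.0420 with the choroid plexus score, which takes up these markers by construction, and ran from -0.26 to 1.23 with 1 library left out. The interaction with sex, 0 genes here, gave 1 gene with RLE size factors, 1584 without the filter, 532 in DESeq2, 3 with GC and length offsets and 0 in the other 3. Genes near Tmem106b stayed at 0 with a 5 Mb window and without a sex term, and in fits added after seeing the data were 1 without the low-count filter, 1 in DESeq2, 3 with GC and length offsets and 0 in the others. Leaving out either female leaves the other to the sex term, so these fits rest on the males. For the other differences the cause was not tested. Timp1 (1.72 CPM in KO), Fcgr2b and Far2 did not pass in 6 of 16 alternatives each.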

Other observations

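The fits with GC and length offsets or a choroid plexus score were added after the data were examined, and the tests on granule cell markers, a common fall, dilution, microglial state and windows of the genome were chosen after the results they bear on were seen. Genes named in the next 2 paragraphs outside the fixed rule were chosen after their values were seen.

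Of the 23 higher genes, 9 belonged to the microglial lists, 3 to the reactive astrocyte list and 10 to no tested list. Several of these 10 are known from macrophages and microglia: the perforin-family gene Mpeg1 rose from 24.4 ± 1.83 to 50.3 ± 8.66 CPM (log2 fold change 1.04, SE 0.09), Emr1, which encodes F4/80, from 3.62 ± 0.14 to 7.84 ± 0.71 CPM (1.11, SE 0.14), and the receptor genes Cd84 (1.19, SE 0.16) and Lilrb4 (2.34, SE 0.30) rose as well (n = 3 each, edgeR adjusted p-values 0.0106 to 0.0363). Lilrb4 was low, at 0.27 ± 0.03 CPM in WT and 1.38 ± 0.30 CPM in KO, below the mean of 1 CPM required of the ranked genes. Cacna1e, which encodes an R-type channel, rose from 159 ± 5.92 to 230 ± 11.6 CPM (edgeR adjusted p = 0.0214) and the ryanodine receptor gene Ryr3 from 36.0 ± 8.53 to 63.3 ± 15.5 CPM (edgeR adjusted p = 0.0359).

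Of the 25 lower genes, 9 belonged to the Purkinje list and 16 to no tested list. Among the latter, Kitl, the ligand of the receptor Kit of molecular layer interneurons, fell from 182 ± 8.61 to 126 ± 16.4 CPM (-0.54, SE 0.07, edgeR adjusted p = 0.0359), and the phosphodiesterase gene Pde5a from 105 ± 5.02 to 74.9 ± 8.14 CPM (-0.49, SE 0.07, edgeR adjusted p = 0.046). Within the Purkinje list the values were spread: Aldoc, the zebrin II antigen, which astrocytes also express, was at -0.07 (SE 0.08) and Plcb3 at -0.08 (SE 0.10), against -1.37 (SE 0.15) for Ebf2, with edgeR adjusted p-values of 0.852, 0.853 and 0.0206.

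The lower Purkinje markers were weighed against 3 explanations. Less cerebellar cortex in the KO pieces would lower granule cell markers too, yet their median was 0.0355. Bias by GC content or gene length would end with those trends removed, yet the Purkinje median was then -0.423, although the trends differed between libraries (Spearman correlation across genes of GC content with each library's deviation from the mean of all 6, -0.613 in KO replicate 1 and 0.411 in KO replicate 3). A common fall of all Purkinje-restricted transcripts would keep Cochran's Q per degree of freedom near 1. A smaller number of these cells would give such a fall if all their subsets were lost alike. Over 18 markers it was 4.12 around a weighted mean of -0.53, and 2.47 around -0.51 without Ebf2, the marker farthest from the rest. The test did not decide, because without Ebf2 the value fell short of the cut-off for rejecting a common fall, set after the data were seen. It also treats the markers as independent, while members of the Purkinje list had an estimated correlation of 0.385. How much of the fall comes from fewer cells and how much from less RNA of these genes per cell cannot be told apart, and both may hold.

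The higher microglial genes were weighed in the same way, except that blood in the pieces was not tested as a source, while red blood cell genes had a median of 0.56 and lymphocyte and neutrophil markers 0.93. Choroid plexus carried into the KO pieces is argued against by a median of 0.726 for the disease-associated list with the choroid plexus score in the model. Dilution by lost Purkinje RNA would raise other cell types alike, yet the highest median among astrocyte, oligodendrocyte and granule cell lists was 0.0355. More microglia with no change of state stays open: members of the disease-associated list alone exceeded those of the homeostatic list alone by 0.331, 0.253 and 0.0795 in the KO libraries and by -0.0839 to 0.0778 in WT. A change of state and a larger number of cells cannot be told apart from 3 libraries whose lowest value lies so near the highest WT value, and both are candidate explanations.

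Around Tmem106b, 13 of 62 genes within 10 Mb (21.0%) had an unadjusted p under 0.05 in edgeR, against 8.96% of all genes (two-sided Fisher exact test, p = 0.00294), although 0 passed after adjustment (1 in DESeq2, 0 in limma-voom, 1 without the low-count filter and 3 with GC and length offsets). A share as high was found in 0 of 119 other windows of 20 Mb (0%). The other splits of the libraries gave at most 6 such genes against 13, some with less power because both females fell in the same group. Yet the count was 8 of 63 in DESeq2 or without WT replicate 3 and 4 of 63 without KO replicate 2. The 13 include Thsd7a, Glcci1, Ica1, Met (0.95, SE 0.32) and Foxp2 (-0.54, SE 0.14, edgeR adjusted p = 0.238), a gene that Purkinje cells express. Flanking sequence of another strain carried with the allele, or regulation at the targeted locus, may underlie this, and the table of counts cannot separate them.

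The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The genotypes gave 48 changed genes and the highest of the other 9 splits gave 1, so that 1 of 10 splits reached 48. The sex term was kept in each split. Where both females fell in 1 group, the group term rested on a single male on that side, so such splits had less power. The counts are therefore not compared on equal terms. For the gene lists, the genotypes gave 14 and the highest other split 15, and 3 of 10 splits reached 14. Camera with the preset correlation called the disease-associated list in 9 of the other 9 splits. It called Purkinje markers and complement genes in 8 each, homeostatic microglia in 6 and reactive astrocyte genes in 2. The genotypes gave the lowest adjusted p for each of these lists. Each of the other splits has 2 mice of 1 genotype and 1 of the other per group, so it can carry part of the genotype difference.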
